A study of Homo sapiens with 6 samples.

How the data were processed

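RNA from cultured U87 cells, a human glioblastoma cell line, was measured on 6 Affymetrix arrays, 1 per sample. Per the labels' protocols, total RNA was taken after 16 h in medium with 10% serum, and biotin-labelled complementary RNA was hybridised. 3 arrays came from cells carrying a dominant negative transgene of IRE1alpha and 3 from cells carrying the empty plasmid. Nothing in the labels says whether replicates were separate cultures, so p-values measure the spread between these samples, which may be technical. The labels name 1 clone for the dominant negative cells and use the plural for the empty-plasmid cells, without assigning a clone to an array.

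The deposited values are linear signal intensities per probe set, 22277 on each array. The submitters' processing notes name GCOS 1.2, the scanner maker's software. The summarisation algorithm and any background step are not given in the sources used here, and no detection calls were used here. The deposited intensities were already scaled: the mean of each array after trimming 2% at each end was 100.0 signal units. Because of that scaling, a change shared by all transcripts of an array would not be seen. The intensity of a dim probe set can hold much background, which was not measured here. A signal below about 13.0, the filter level defined next, is therefore not called present or absent. A ratio against such a signal is imprecise. The number of arrays limits the precision of every value.

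Intensities were transformed to log2(signal + 1.75). The pseudocount of 1.75 is the 20th percentile of all values, and it makes the fold changes of dim genes smaller than the ratio of their signals. Gene names came from the platform annotation supplied with the series. 19064 probe sets had 1 gene symbol, 1043 had several and 2108 had no listed gene; the other 62 were control probe sets. Of the 19064, 19052 matched a gene of the GRCh38.p14 RefSeq table by identifier and 12 kept the platform symbol. No genome coordinates are printed, because the arrays' annotation names no build. For each of 11963 genes the probe set with the highest mean log2 signal over all 6 arrays was used. The 7178 genes with a mean above the 40th percentile, which equals a signal of 13.0, were tested. This filter leaves out some genes that were lost almost completely in 1 group, because it acts on the mean log2 signal.

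The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, all 6 arrays, no covariate, two-sided). Adjusted p-values are limma's, by the Benjamini-Hochberg method, with a threshold of 0.05. Fold changes are dominant negative minus control on the log2 scale, with their standard errors (SE). Gene lists were fixed before the data were examined: 25 lists, of which 22 had at least 2 tested members. They were tested with limma's camera (preset correlation of 0.01, adjusted over 22 lists), with camera's estimated correlation, and with fry. Lists overlap, and counts in each list are given over all genes tested and adjusted over the list alone. None of the 7 list calls held with an estimated correlation. In that setting camera also takes its degrees of freedom from the residuals of the 6 arrays, not from the number of genes. A call lost there is therefore not by itself evidence of correlated genes. The genes named in the text were chosen by a rule fixed beforehand: ERN1 and XBP1, the 12 largest increases and 12 largest decreases past the threshold whose arrays did not overlap between groups, and up to 4 changed members of each list with the largest changes. Other genes named for a list were chosen after their values were seen. Where the mean of a group lies under the filter level, as for 27 of the 97 genes named by the rule besides ERN1 and XBP1, the size of the log2 change depends on the pseudocount. It can also do so above that level: with a pseudocount of 16, 40 of the 97 moved over 1.5 times, these 27 among them.

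In simulated data with the means and residual spread of the 7178 genes in this comparison, the limma test recovered 3.6% of genes changed by 0.5, 55.6% of genes changed by 1, 90.4% of genes changed by 2 and 98.8% of genes changed by 4 on the log2 scale, with 5.62% false calls. Only 200 genes were changed per run, against 2468 past the threshold in the data. Both groups were given the same spread, unlike the data, so these rates need not hold for this comparison. Camera called 10 of 10 shifted lists and 0 of 10 unshifted lists in simulated data. Genes were simulated as independent there, and every member of a shifted list moved by 1. In the data the estimated correlation within a list reached 0.76, so the simulation does not check the list calls. The alternatives were other pseudocounts, filters, scalings, probe set choices and variance models, array weights, the replicate number as a block, and each array left out in turn. With 1 array fewer a call can end although the size of the change hardly moves. A call that ended does not by itself show that the change rested on that array. A pseudocount of 16 and the removal of control array 2 and dominant negative array 3 together were added after the data were seen.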

Results

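The series compared U87 glioblastoma cells expressing a dominant negative form of IRE1alpha, an endoplasmic reticulum stress sensor encoded by ERN1, with U87 cells carrying the empty plasmid. Its stated purpose was to find genes linked to tumour invasion and blood vessel formation. Expression was measured on 6 arrays, 3 per group, for 7178 genes above the filter level. Scaled array signals had medians between 18.4 and 21.03 units, and between 59.8% and 60.7% of the 11963 annotated genes lay above the filter level on each array.

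The arrays separated by group. Correlations of log2 signals between arrays were 0.974 to 0.979 within the dominant negative group, 0.959 to 0.967 within the control group, and 0.930 to 0.951 between groups. The first principal component held 70.5% of the variance and parted the groups. Control arrays were the more variable: the median SD of a gene was 0.29 among controls and 0.17 among dominant negative arrays on the log2 scale, and 70.9% of genes had the larger SD in the controls. RNA quality measures did not separate the groups. The 3′ to 5′ signal ratio of ACTB was 1.19 ± 0.0240 (SD, n = 3) in controls and 1.31 ± 0.290 (SD, n = 3) in dominant negative cells (exact permutation test, two-sided, p = 0.7), and that of GAPDH was 0.901 ± 0.0284 and 0.911 ± 0.0250 (exact permutation p = 0.6; both are 0.933 after adjustment over 4 measures, and 0.1 is the smallest p that 3 against 3 allows). Dominant negative array 3 stood apart, with an ACTB ratio of 1.64 and hybridisation spike-ins 1.75 times the control mean.

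The targeted transcript was not measured informatively. ERN1 had signals of 12.3 ± 1.53 (SD, n = 3) in controls and 11.1 ± 1.58 (SD, n = 3) in dominant negative cells, below the filter level of 13.0, with a log2 change of -0.13 (SE 0.32; limma adjusted p = 0.83 in a fit without the filter). Its single probe set need not lie within the transgene, so this value does not check the labels. XBP1, whose transcript IRE1alpha splices, fell from 232 ± 31.3 to 123 ± 8.97 units (SD, n = 3 each), a log2 change of -0.90 (SE 0.18; limma adjusted p = 0.0045). The array measured total XBP1 transcript, not its splicing.

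Expression differed widely between the groups. Of 7178 genes, 2468 passed the threshold in limma, 1283 higher and 1185 lower in dominant negative cells, and 1133 of them changed at least 2-fold, 640 up and 493 down. Of the 2468 genes 52.0% were higher, but of those past the threshold 48.7% after quantile normalization, 45.1% with equal medians and 49.1% with a 60th percentile filter, so neither direction prevailed in all settings. The 3 arrays of one group lay entirely above those of the other for 50.2% of genes, where chance gives 10%. The number of genes changed was 1446 without dominant negative array 2 and 1487 without dominant negative array 3.

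TAGLN, an actin-binding protein of smooth muscle, rose from 8.74 ± 5.45 to 674 ± 80.4 units (log2 change 6.19, SE 0.41; limma adjusted p = 1.4e-05). EDN1, the vasoconstrictor endothelin, rose by 5.64 (SE 0.35), and LBH, a transcription cofactor, by 4.73 (SE 0.21). The small proteoglycans LUM and DCN rose by 5.02 (SE 0.56) and 4.28 (SE 0.21), the basement membrane proteoglycan HSPG2 by 4.32 (SE 0.41), and the fibrillar collagen COL5A1 by 4.08 (SE 0.22), from 101 ± 26.6 to 1699 ± 247 units. THBS1, an inhibitor of angiogenesis, rose from 8.81 ± 8.56 to 255 ± 27.4 units (4.90, SE 0.46), and all 5 of its probe sets rose in value. The steroid enzyme HSD17B2 rose by 5.41 (SE 0.91), the BMP antagonist CHRDL1 by 4.97 (SE 0.88), FARP1 by 4.15 (SE 0.86) and the adhesion molecule CADM1 by 4.14 (SE 0.48). Except for HSD17B2 (0.0024), CHRDL1 (0.0030) and FARP1 (0.0057), limma adjusted p-values of these genes were 0.00033 or lower. Control means lay under the filter level of 13.0 for 5 of the 12 increases. Log2 sizes depend on the pseudocount, also above that level, so the order of the 12 is not interpreted. With a pseudocount of 16, added after the data were seen, the 12 rose by 2.56 to 4.82. Of the 12, 11 moved over 1.5 times, among them CHRDL1 (3.57) and FARP1 (2.62). Their control means lay above the level only through control array 3 (61.7 and 49.7 units), and their other control arrays lay under it. Several of these sizes moved over 1.5 times, to a larger or smaller value, when 1 control array was left out. HSD17B2 rose by 6.78 without control array 2, by 4.66 without control array 1 and by 4.77 without control array 3. CHRDL1 rose by 6.21 without control array 3 and 3.90 without control array 1. FARP1 rose by 5.43 without control array 3 and 3.32 without control array 2. LUM rose by 5.72 without control array 3 and 4.30 without control array 2, and THBS1 by 5.52 without control array 3.

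DNAJC15, a mitochondrial co-chaperone, fell from 873 ± 420 to 5.52 ± 1.08 units (log2 change -6.80, SE 0.33; limma adjusted p = 2.8e-06). CXCL8, the neutrophil chemokine interleukin-8, fell from 629 ± 332 to 5.77 ± 3.05 units (-6.34, SE 0.38), and both of its probe sets fell in value. ASS1, the urea cycle enzyme argininosuccinate synthase, fell by 6.31 (SE 0.32) and the channel AQP9 fell by 5.88 (SE 0.27). CXCL2 changed by -5.82 (SE 0.55), CSF3 by -5.78 (SE 0.69) and IL6 by -5.32 (SE 0.66). MMP3, stromelysin, fell from 848 ± 361 to 16.4 ± 3.26 units (-5.47, SE 0.31), and BDKRB1, a bradykinin receptor, fell by 5.38 (SE 0.23). PRSS3 (-5.82, SE 0.42), PNMA2 (-5.56, SE 0.56) and the glutamate transporter SLC1A1 (-5.48, SE 0.63) also fell. The probe sets chosen for CXCL8, CXCL2, PRSS3 and DCN are of a type that can bind related transcripts. Limma adjusted p-values of all 12 genes were 0.000495 or lower. Dominant negative means lay under the filter level of 13.0 for 11 of the 12 decreases, so their order is not interpreted either: with a pseudocount of 16 the 12 changed by -5.25 to -3.03. All 12 moved over 1.5 times. The size depended on control array 2 for CXCL2 (-5.22 without it), IL6 (-4.52), PNMA2 (-6.29) and SLC1A1 (-6.30), and for IL6 also on control array 3 (-5.93 without it).

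**Figure D1:**
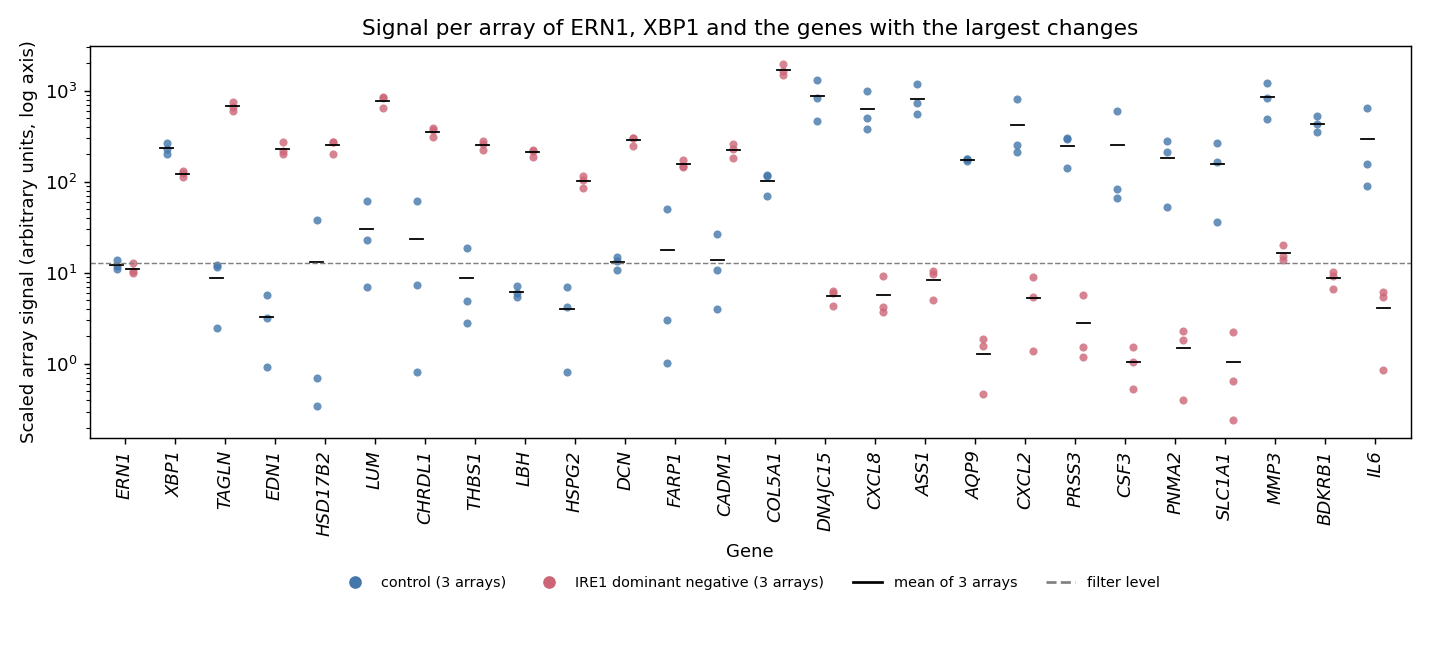
Scaled array signal (log axis) of ERN1, XBP1 and the 12 increases and 12 decreases of the largest fitted size, with 1 point per array, black bars at the mean of 3 arrays and a dashed line at the filter level of 13.0. XBP1 was lower on all 3 dominant negative arrays, ERN1 overlapped, and for the 24 other genes the groups did not overlap.

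Matrix genes rose together. Of 23 tested members of the collagen and matrix list, 22 rose and 0 fell (22 also when adjusted over the list alone), with a median log2 change of 1.34. The fibrillar collagen COL1A1 rose from 210.0 ± 174 to 2574 ± 514 units (3.94, SE 0.50), although 1 of its 4 probe sets was lower in value. COL1A1 changed by 4.59 without control array 1 and by 3.33 without control array 2. The crosslinking enzyme LOX rose from 354 ± 2.04 to 2473 ± 419 units (2.78, SE 0.16), and COL5A2, COL3A1, FBN1 and FN1, chosen after their values were seen, rose by 3.09, 2.95, 2.17 and 1.17. The FN1 call ended without dominant negative array 3 (limma adjusted p = 0.053). The camera adjusted p was 2.1e-13, and the adjusted p was 0.40 with an estimated correlation.

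Neither angiogenesis list passed, and the difference between them was not tested. Of 13 tested anti-angiogenic genes, 5 rose and 2 fell, the same counts when adjusted over the list alone. DCN and THBS1 rose as given above, and the metalloprotease inhibitor TIMP2 rose by 2.38 (SE 0.45; 1.78 without control array 2). TFPI2, a serine protease inhibitor, fell from 2365 ± 321 to 98.3 ± 1.45 units (-4.56, SE 0.16; limma adjusted p = 6.4e-07). Camera gave this list an adjusted p of 0.089. It passed without control array 3, with an adjusted p of 0.028 and 7 members up, without dominant negative array 2, with 0.040, with the mean of each gene's probe sets, with 0.029, with arrays set to equal medians, with 0.0496, and in fry, with 0.038. Control array 3 lay 0.50 above the control mean of this list. Of 23 tested pro-angiogenic genes, 7 rose and 5 fell (7 and 5 adjusted over the list alone). The 7 were EDN1, given above, ADM (2.11, SE 0.32), and, named after their values were seen, the angiopoietin ANGPT1 (1.89), FGF1 (1.76), PDGFC (1.31), CCN1 (1.13) and PDGFA (0.83). ANGPT1 changed by 1.10 without control array 2 and 2.48 without control array 1, and its call ended without any dominant negative array (limma adjusted p of 0.064 to 0.092). That of PDGFA ended without any single array except control array 2 (0.067 to 0.16). The 5 were CXCL8, IL6, EREG, an EGF receptor ligand (-4.92, SE 0.41), and IL1B and HBEGF (-4.12 and -2.06, named after their values were seen; 2 of 3 HBEGF probe sets fell in value). IL1B had a control SD of 638 around a mean of 459 units, and changed by -2.88 without control array 2 and by -4.84 without control array 1. The median of the list was 0.14 and its mean -0.35, and camera put it at an adjusted p of 0.95. The median turned to -0.09 without control array 3 and -0.01 without dominant negative array 2, and the mean lay between -0.59 (without dominant negative array 1) and -0.21 (without control array 2). HGF, hepatocyte growth factor, left out by the filter and named after its values were seen, measured 82.2 ± 54.9 units in controls and 0.488 ± 0.470 in dominant negative cells (log2 change -5.06, SE 0.47; limma adjusted p = 0.00031 in a fit without the filter), and all 5 of its probe sets were lower in value. With no filter, 33 pro-angiogenic genes were tested, 6 rose and 6 fell, and the median was -0.05. VEGFA, also singled out afterwards, measured 786 ± 81.9 units in controls and 879 ± 79.3 in dominant negative cells (log2 change 0.16, SE 0.15; limma adjusted p = 0.43).

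Inflammatory transcripts fell together. Of 13 tested members of the inflammatory and NF-kB list, 0 rose and 11 fell (12 fell when adjusted over the list alone), with a median log2 change of -2.14. Besides CXCL8, CXCL2 and IL6, CXCL3 fell from 191 ± 154 to 5.71 ± 5.07 units (-4.59, SE 0.69). CXCL3 changed by -3.95 without control array 2, -5.30 without control array 3 and -3.97 without dominant negative array 2. The inhibitor NFKBIA and the prostaglandin synthase PTGS2, named afterwards, changed by -2.14 and -2.09. PTGS2 changed by -1.29 without control array 2 and by -2.73 without control array 1, and its call ended without dominant negative array 2 (limma adjusted p = 0.065) or 3 (0.078). The camera adjusted p was 4.9e-07, and the adjusted p was 0.56 with an estimated correlation. Control array 2 had the highest mean of this list, 0.92 log2 units above the control mean, and 8 members fell when control array 2 and dominant negative array 3 were both left out. Of 15 tested interferon response genes, 0 rose and 5 fell (1 rose and 7 fell adjusted over the list alone), among them IFI44L (-2.91, SE 0.38), OASL (-1.86, SE 0.21), RIGI (-1.72, SE 0.29) and IFI35 (-1.16, SE 0.27). Camera gave an adjusted p of 0.039, and the adjusted p was 0.58 with an estimated correlation. The interferon call ended without control array 1 (adjusted p = 0.19), control array 3 (0.050) or dominant negative array 1 (0.063), with 1 member up without control array 3, and under 5 settings of the filter, the probe sets and the array weights (0.095 to 0.22).

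Hypoxia and glycolysis genes rose. Of 28 tested members, 18 rose and 0 fell (23 rose when adjusted over the list alone), with a median log2 change of 0.93. NDRG1 rose from 227 ± 173 to 921 ± 51.6 units (2.26, SE 0.40), the aldolase ALDOC by 2.26 (SE 0.35), the glucose transporter SLC2A1 by 2.23 (SE 0.28) and the vasodilator peptide ADM by 2.11 (SE 0.32). The camera adjusted p was 8.3e-08, and the adjusted p was 0.58 with an estimated correlation. 12 members rose when control array 2 and dominant negative array 3 were both left out. The controls themselves differed, from -0.34 in array 2 to 0.43 in array 3 around their mean for this list.

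Cell cycle genes split. Of 32 tested members, 16 rose and 4 fell (18 and 4 adjusted over the list alone). Cyclin E2 (CCNE2) rose from 107 ± 16.5 to 427 ± 66.1 units (1.98, SE 0.19), the phosphatase CDC25A by 1.76 (SE 0.27) and the replication helicase subunit MCM3 by 1.57 (SE 0.19). The 4 that fell were the mitotic regulators CCNB1, from 1106 ± 113 to 433 ± 17.0 units (-1.35, SE 0.14), PLK1 (-1.31), CDC20 (-0.92) and CCNB2 (-0.54), the last 3 named afterwards. Mitotic members did not all fall. CENPF and KIF11, also named afterwards, passed the threshold and were at least 2-fold higher in dominant negative cells, with means of 318 and 282 units there. The CCNB2 call ended without control array 3 or any dominant negative array (limma adjusted p of 0.054 to 0.11). The camera adjusted p was 0.0056, the adjusted p was 0.63 with an estimated correlation, and in fry the list did not pass (adjusted p = 0.059).

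Of 25 tested XBP1 targets, 1 rose and 7 fell (1 and 8 adjusted over the list alone; camera adjusted p = 0.23). The co-chaperone DNAJB9 changed from 366 ± 188 to 134 ± 3.40 units (-1.32, SE 0.30; limma adjusted p = 0.0090), SEC24D by -0.97 in 1 of 3 probe sets with the other two going up in value, DNAJC10 by -0.85 and GFPT1 by -0.79. The limma calls of SEC24D, DNAJC10 and GFPT1 ended without dominant negative array 3 (adjusted p of 0.052, 0.080 and 0.082), and that of DNAJC10 also without dominant negative array 2 (0.13), control array 2 (0.094) or control array 3 (0.050). Fewer XBP1 targets fell without control array 2 or dominant negative array 2 (4 each) or dominant negative array 3 (2), and 2 rose without control array 1 or 2 and 0 without any dominant negative array. Of 18 tested ER chaperone genes, 3 rose and 1 fell, and the same was found adjusted over the list alone (camera adjusted p = 0.86). P4HB rose by 0.95 (SE 0.22), CRELD2 by 0.90 (SE 0.21; adjusted p = 0.054 without dominant negative array 3) and PDIA3 by 0.77 (SE 0.16), while FKBP2 fell by 1.22 (SE 0.21), and 2 members fell without control array 1. Of 27 tested ATF4 and CHOP targets, 3 rose and 7 fell, with a median log2 change of -0.59 (3 and 9 adjusted over the list alone; camera adjusted p = 0.026, and adjusted p = 0.79 with an estimated correlation). ATF3 fell from 112 ± 29.5 to 14.4 ± 0.340 units (-2.79, SE 0.24), while STC2, a secreted glycoprotein, rose by 3.20 (SE 0.46; 2.54 without control array 1). DDIT3 and TRIB3 changed by -1.81 (SE 0.53) and -1.61 (SE 0.55). Control arrays 1 and 2 lay -0.70 and 0.62 from the control mean of this list, and its call ended without control array 2 (camera adjusted p = 0.26) or dominant negative array 1 (0.058), with a 60th percentile filter (0.15) and in fry (0.28). The median was -0.24 without control array 2, and 1 member rose without control array 1 or any dominant negative array. Of this list 16 members fell without control array 1, 4 without control array 2 or dominant negative array 1, and 3 without dominant negative array 2 or 3. The calls of DDIT3 and TRIB3 ended without control array 2 (-1.34 and -0.88; limma adjusted p of 0.076 and 0.077). The DDIT3 call also ended without control array 3 (0.052), dominant negative array 1 (0.086) or 3 (0.070), and the TRIB3 call without any dominant negative array (0.099 to 0.12). With 1 dominant negative array left out TRIB3 changed by -1.53 to -1.69, close to its size with all arrays. Without control array 1 DDIT3 and TRIB3 changed by -2.55 and -2.24. Of 11 tested transcripts known as substrates of IRE1-dependent decay, 7 rose and 3 fell (7 and 4 adjusted over the list alone), with a median log2 change of 0.88. Camera gave these transcripts an adjusted p of 0.22, and the list passed in fry (adjusted p = 0.034). GALNT10 rose by 1.66 (SE 0.25), COL6A1 by 1.21 (SE 0.18, with 6 of 8 probe sets up in value) and PDGFRB by 1.15 (SE 0.28; limma adjusted p = 0.051 without dominant negative array 3). SCARA3 fell by 1.40 (SE 0.28). SPARC, a matrix glycoprotein named afterwards, rose from 822 ± 134 to 1739 ± 195 units (1.09, SE 0.16).

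Genes of invasion and adhesion moved in both directions. Of 23 tested proteases and inhibitors, 5 rose and 7 fell (8 and 7 adjusted over the list alone; camera adjusted p = 0.95). MMP3 fell as given above and the aggrecanase ADAMTS5 fell from 104 ± 87.8 to 9.07 ± 0.243 units (-2.87, SE 0.58; -3.63 without control array 1 and -2.19 without control array 2), while the plasminogen activator PLAT rose from 47.8 ± 16.0 to 278 ± 15.4 units (2.55, SE 0.25). Without control array 3, 9 members rose. Of 20 tested adhesion receptors, 9 rose and 4 fell, the same adjusted over the list alone (camera adjusted p = 0.14). The syndecan SDC2 rose by 2.41 (SE 0.47; 3.04 without control array 3), and the integrins ITGA7, ITGB3 and ITGA2 changed by -3.20 (SE 0.70; -2.30 without dominant negative array 2), -2.21 (SE 0.43) and -2.14 (SE 0.40). Of 21 tested TGF-beta targets, 8 rose and 3 fell (8 and 4 adjusted over the list alone; camera adjusted p = 0.079). Besides TAGLN, the growth factor CCN2 rose by 2.18 (SE 0.29), PMEPA1 by 2.17 (SE 0.26) and the smooth muscle actin ACTA2 by 3.27 (SE 0.26), the last in 1 of 2 probe sets. The TGF-beta list passed without control array 1 (adjusted p = 0.035) or control array 3 (0.039), with array weights, equal medians or no filter (0.040 to 0.0496), and in fry (0.0086), and 5 of its members fell without control array 2. The adhesion list passed with a 60th percentile filter (0.011) and in fry (0.034).

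Of 7 tested neural and proneural markers, 4 rose and 0 fell (4 and 0 adjusted over the list alone). The transcription factor SOX4 rose from 18.5 ± 10.6 to 123 ± 7.89 units (2.80, SE 0.41), SOX9 by 2.64 (SE 0.36), the glutamate transporter SLC1A3 by 1.44 (SE 0.28) and NCAM1 by 0.74 (SE 0.24), whose call ended without any single array except control array 2 (adjusted p of 0.071 to 0.13). The camera adjusted p was 0.012, and the adjusted p was 0.40 with an estimated correlation. That correlation was -0.094, below the preset 0.01, so a larger correlation does not account for the loss. The unadjusted camera p was 0.0026 with the preset and 0.036 with the estimated correlation, which also lowers the degrees of freedom. With no filter on signal, 24 members were tested and the list did not pass (adjusted p = 0.44), nor did it with a 60th percentile filter (0.099) or the mean of each gene's probe sets (0.12). Of 21 mesenchymal glioblastoma markers, 3 rose and 5 fell, also over the list alone (camera adjusted p = 0.95). LOX rose as above, CHI3L1 by 1.63 (SE 0.38) with 2 of 3 probe sets up in value, and CASP1 and CASP4, inflammatory caspases, fell by 2.47 (SE 0.25) and 1.69 (SE 0.21), CASP4 in 1 of 2 probe sets. Without dominant negative array 1, 5 of these markers rose.

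The remaining lists did not pass in camera. Of 16 antigen presentation genes, 5 rose and 3 fell (5 and 6 adjusted over the list alone; camera adjusted p = 0.95). The class II gene HLA-DRA fell from 320 ± 266 to 14.2 ± 3.12 units (-3.92, SE 0.58; -4.69 without control array 2 and -3.25 without control array 3) and HLA-DPA1 fell by 2.34 (SE 0.47; -2.93 without control array 2, -1.75 without control array 3), while the probe set of HLA-G, which can bind related class I transcripts, rose by 1.28 (SE 0.34), lost without dominant negative array 1 (adjusted p = 0.066) or dominant negative array 3 (0.051). PSMB10 changed by -1.06 (SE 0.31), lost without dominant negative array 3 (adjusted p = 0.10), dominant negative array 2 (0.061), control array 1 (0.068) or control array 3 (0.051). Control arrays 2 and 3 lay -0.55 and 0.62 from the control mean of this list. Of the list 6 members fell without control array 2 and 3 rose without dominant negative array 1 or 3. Of 15 lipid synthesis genes, 4 rose and 3 fell (camera adjusted p = 0.71), with the desaturase FADS2 up by 2.60 (SE 0.31) ACSL4 down (-1.28, SE 0.20), ELOVL6 down (-0.91, SE 0.21) and ACACA up by 1.01 (SE 0.24) in 1 of 2 probe sets. The ACACA call ended without dominant negative array 2 (limma adjusted p = 0.056). Of 15 cholesterol synthesis genes, 1 rose, DHCR7 by 0.71 (SE 0.16; camera adjusted p = 0.95), and 2 rose without control array 1 and 1 fell without control array 3. Of 15 cytosolic heat shock genes, 1 rose and 6 fell (camera adjusted p = 0.32), with DNAJB4 up by 1.61 (SE 0.18) and HSPB8 and HSPE1 down (-1.46, SE 0.35, and -1.12, SE 0.18). HSPA4 changed by -0.85 (SE 0.16), with 3 of 4 probe sets down in value. Without control array 2 or dominant negative array 3, 3 heat shock genes fell. Of 16 p53 targets, 1 rose and 5 fell (camera adjusted p = 0.35; 0.034 in fry), with GDF15 falling from 128 ± 71.0 to 15.8 ± 4.39 units (-2.71, SE 0.45; -3.31 without control array 1), BAX and TNFRSF10B changing by -1.34 (SE 0.31) and -1.01 (SE 0.17), and SUSD6 rising by 1.06 (SE 0.21). Of 10 circadian clock genes, 2 rose and 2 fell (camera adjusted p = 0.64), with BHLHE41 changing by -1.02 (SE 0.19), CRY1 by -0.84 (SE 0.24), CLOCK by 0.79 (SE 0.22) in 1 of 2 probe sets and PER3 by 0.78 (SE 0.23). The limma calls of CRY1, CLOCK and PER3 each ended without dominant negative array 2 or 3 (adjusted p of 0.054 to 0.098), that of CRY1 also without control array 2 (0.066), and that of PER3 without control array 1 (0.055), control array 2 (0.064) or dominant negative array 1 (0.11). Without dominant negative array 2 or 3, 0 clock genes rose and 1 fell. Without control array 1 or 2 or dominant negative array 1, 1 rose, and 1 fell without control array 2. The counts of the lipid, cholesterol, heat shock, p53 and clock lists were the same when adjusted over the list alone. Markers of other cell types were near background: median signals were 3.05 and 2.71 units for endothelial, 4.25 and 4.45 for haematopoietic and 4.62 and 2.21 for epithelial genes in control and dominant negative cells. In each of the last 2 lists 1 member was tested, CSF1R (0.88, SE 0.29, from 31.4 ± 11.9 to 56.4 ± 2.31 units, not past the threshold without control array 2, at an adjusted p of 0.089, or without any dominant negative array, at 0.096 to 0.11) and MUC1 (1.93, SE 0.26).

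**Figure D2:**
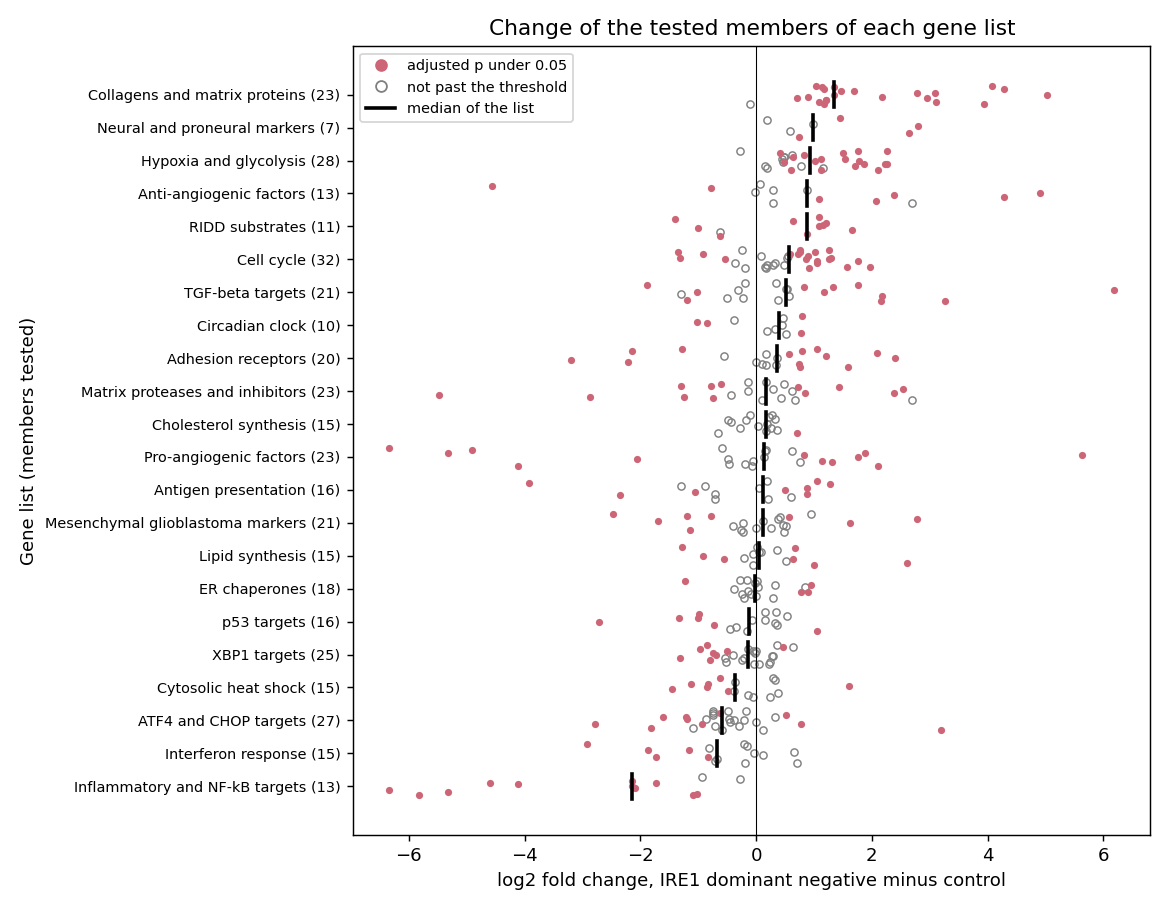
Log2 fold change (dominant negative minus control) of each tested member of the 22 gene lists, with filled points for members past an adjusted p of 0.05, open points for the others and a black bar at the median of the list. Collagens and matrix proteins had the highest median, 1.34, and inflammatory and NF-kB targets the lowest, -2.14.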

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

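The gene-level comparison left out probe sets with no listed gene or with several genes. Of 1428 such probe sets above the filter, 196 were higher in dominant negative cells than in controls at a limma adjusted p under 0.05 and 161 were lower. They were singled out as signal outside the reported comparison. The shares, 13.7% and 11.3%, compare with 17.9% and 16.5% of named genes, and the probe sets are not named here. Dixon's test of a single outlying value was not run in groups of 3.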

How the results depend on the processing

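Under the planned settings with all 6 arrays and 1 value per gene, the number of genes changed (2468) lay between 1838 and 2841, and the number of genes changed at least 2-fold (1133) between 681 (60th percentile filter, fewer genes tested) and 1291 (no filter). Testing all 13329 probe sets gave 3876 and 2023, more features being tested. Leaving out 1 array gave 1446 to 2671 genes changed, 934 to 1266 genes changed at least 2-fold, and 5 to 8 lists against 7. Leaving out control array 2 and dominant negative array 3 together, chosen after seeing the data, gave 1180 genes changed, with fewer arrays. The estimated correlation left 0 lists in limma's camera (2 at an unadjusted p under 0.05), and fry, which does not set a list against other genes, gave 10. In fry the ATF4 and CHOP (adjusted p = 0.28) and cell cycle (0.059) lists were lost, and 5 were gained: TGF-beta (0.0086), IRE1-dependent decay, p53 and adhesion (0.034 each) and anti-angiogenic (0.038). XBP1 was lower and past the threshold in every setting run for it (-0.81 to -0.997 without 1 array), and ERN1 passed in none. Arrays with the same number did not deviate together (correlations across genes of -0.10, 0.06 and 0.02), and not every array correlated best with its own number. With the replicate number as a block, 2276 genes changed, 2196 of them among the 2468, 7 lists passed, and XBP1 had an adjusted p of 0.0111.

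Of 1884 values of 97 named genes, 1802 had the same direction and side of the threshold, 80 fell short of it and 2 turned sign: gene SEC24D with the mean of its probe sets (0.024) and gene HSPA4 without probe sets that can bind several transcripts (0.046). Of 484 list means, 19 turned sign, all in lists that did not pass. They were Mesenchymal glioblastoma markers (no filter -0.030, quantile normalization -0.071, equal medians -0.059, mean of probe sets -0.078, both arrays out -0.11), Cholesterol synthesis (60th percentile filter -0.011, equal medians -0.036, mean of probe sets -0.061, array weights -0.00030, both arrays out -0.0086), Antigen presentation (60th percentile filter 0.040), Lipid synthesis (60th percentile filter -0.014) and Circadian clock (mean of probe sets -0.069). Without 1 array, means ranged from -0.14 to 0.10 for Matrix proteases and inhibitors, -0.096 to 0.17 for Cholesterol synthesis, -0.045 to 0.18 for ER chaperones and -0.054 to 0.051 for Mesenchymal glioblastoma markers. The cause was not tested. With no detection calls, signal over background cannot be judged below 13.0 units.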

Other observations

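The tests of this part were chosen after the results were seen, except the count over splits of the arrays. The gene groups of the next paragraphs were put together after the largest changes were seen, some of their members are also in the fixed lists, and no enrichment was tested. Of 15 tested contractile and actin-binding genes, 12 rose, 1 fell and 2 did not pass, with a median log2 change of 1.24. TAGLN and ACTA2 are among them, as are ACTG2, from 12.4 ± 3.80 to 216 ± 23.5 units (SD, n = 3 each), the myosin light chain MYL9 (3.54, SE 0.36), its kinase MYLK (2.71, SE 0.27) and the focal adhesion gene ACTN1 (1.24, SE 0.23). SMTN fell by 1.09 (SE 0.30), a call that ended without control array 2 (limma adjusted p = 0.065) or dominant negative array 2 (0.066) or 3 (0.086).

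Of 13 tested aldo-keto reductase and NRF2 target genes, 1 rose and 7 fell. AKR1C1 fell from 1403 ± 207 to 190.0 ± 12.8 units. AKR1C2, a close paralog whose probe sets can share its signal, fell from 1276 ± 293 to 121 ± 3.57 units. AKR1B10 (-2.46), HMOX1 (-1.24), PGD (-1.05), GCLM (-0.78) and TALDO1 (-0.47) also fell, and GCLC rose (0.94). Among those that did not pass were NQO1 (0.54, SE 0.23) and TXNRD1 (-0.01, SE 0.25). TXNRD1 changed by -0.29 without control array 1 and by 0.27 without control array 2. Of 8 tested genes of retinoid metabolism and response, 1 rose, 3 fell and 4 did not pass. The retinaldehyde enzymes ALDH1A3 (-4.50, SE 0.21) and DHRS3 (-3.27, SE 0.34) and the receptor RARG (-1.45, SE 0.35) fell, and the receptor RARB rose (2.47, SE 0.39). RARRES2, left out by the filter, had a log2 change of 3.53 (SE 0.37; limma adjusted p = 0.00046 without the filter). Of 8 tested MHC class II genes, 0 rose and 5 fell, and of 8 genes of the insulin-like growth factor axis, 4 rose and 1 fell, with IGFBP6 falling from 1116 ± 116 to 451 ± 95.5 units and IGFBP5 rising by 3.35 (SE 0.51; 3.99 without control array 3).

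Log2 changes of neighbouring genes correlated (Spearman 0.098 across 7155 pairs, genes not being independent, against at most 0.047 in 1000 shuffles), and the medians of 13 of 23 chromosomes differed from random gene sets. Several of these shifts did not span the chromosome. The genes before and after the middle gene had medians of 0.57 and 0.03 on chromosome 6, 0.29 and 0.03 on chromosome 4, and 0.01 and -0.35 on chromosome 18. After subtraction of each chromosome's median, 2373 genes passed, 2173 of them among the 2468.

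The 210 tested genes of chromosome 20, picked for having the most extreme median, had a median of 0.33, and 74.8% of them were higher in dominant negative cells. Without the 5 highest of its 21 windows of 10 neighbouring genes, the median of the other 160 genes was 0.23 (lower bound of a bootstrap over windows, 0.14), which argues against a few clusters of regulated neighbours as the whole cause. The median was 0.30 after quantile normalization, where random gene sets reached 0.20, which argues against scaling as the whole cause. Genes before and after the middle gene of the chromosome, and its dim and bright genes, were all shifted by at least 0.29, past 0.17, the upper limit of random sets (two-sided, 0.05), so a copy number difference between the cell lines is a candidate explanation. Against control arrays 1, 2 and 3 taken singly the chromosome 20 median was 0.36, 0.24 and 0.44, so the controls also differed here. Random sets ignore the correlation of neighbours and the picking of this chromosome, and an effect of the transgene on these genes stays open as untested.

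The control arrays spread more than the dominant negative arrays, also among genes above the median signal (72.1% had the larger SD in controls), which argues against dim probe sets as the cause. Dominant negative cells mixed into control array 3 would move genes at like levels in both groups little, yet 67.5% of 889 genes with a log2 change under 0.1 either way had the larger SD in controls, which argues against mixing as the whole cause. Mixing as part of the cause stays open: 271 abundant genes at least 2-fold higher in dominant negative cells implied shares with a median of 8.84% (quartiles -4.32% and 22.2%). On the first principal component control array 3 lay nearest the dominant negative arrays (-29.0, against -38.4 and -42.8). However, 11 of the 271 genes had less signal in control array 3 than the median share of their lowest dominant negative array. Of the 11, 4 were over 2-fold below but at signals under the filter level of 13.0, and 7 by less. TAGLN, among the 4, stayed over 2-fold below the 53.3 units needed with its signal of 12.2 raised to that level. On chromosome 14, picked for the largest deviation of this array, control array 3 lay 0.59 below the mean of the other controls over 251 genes, by at least 0.45 before and after its middle gene and in dim and bright genes (lower limit of random sets, -0.08, which does not allow for the picking). Control array 3 also deviated from the other controls on chromosomes 22 (0.33), 9 (-0.29) and 17 (0.29), while no chromosome set any dominant negative array apart from the other two by more than 0.0802, so control cultures that differed in chromosome content may be part of the cause (-0.45), and clone differences cannot be separated from the transgene in this design.

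Of 10 splits of the 6 arrays into 3 and 3, 1 gave as many genes as the real grouping (2468), namely the real one, and the highest of the others gave 0 in limma. At an unadjusted p under 0.05 the others gave 30 to 185 genes and the real grouping 3304. Every other split puts arrays of both groups on each side, so the real difference widens the spread within each side. Low counts in those splits follow from that and are not evidence for the real grouping. In addition, 10 splits are too few for a share under 0.05. MMP1, a collagenase left out by the filter, had signals of 49.9 ± 21.3 in controls and 0.394 ± 0.504 in dominant negative cells.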
